A study of Arabidopsis thaliana with 16 samples.

How the data were processed

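Total RNA from pooled root tips of 5-day-old Arabidopsis thaliana seedlings was hybridized to 16 Affymetrix ATH1 arrays, 2 biological replicates for each of 4 genotypes (Columbia wild type, wer-1 myb23-1, cpc-1 try-82 and scm-2) on each of 2 media. Per the labels' protocols, seedlings were moved for 1 hour to standard medium or to medium with 140 mM NaCl, about 30 roots were cut about 5 mm above the tip and pooled per replicate, and biotin-labelled cRNA was made by one-cycle amplification. The deposited values are linear intensity values per probe set, made by the authors with MAS5 per the submitters' processing notes; its version, scaling target and background settings are not given in the sources used here, and detection calls were not used here. In the deposited table each array held 22810 positive values, and the mean after trimming 2% of the values at each end was 250.03 on every array, so the arrays had been scaled to a common trimmed mean.

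Arrays were grouped by the genotype and medium in their titles. For the mutant arrays whose titles and descriptions name standard medium, the growth medium entry of the labels names NaCl instead, and for cpc try and scm it gives another number of days; the titles and descriptions were followed. The values, which were not used for grouping, spoke against the medium entry: on the leading principal component the mutant arrays titled standard lay from -44.5 to -35.8 beside the wild type standard arrays (-44.5 and -37.0), and all salt arrays lay from 30.2 to 54.2. Replicate numbers were not treated as pairs: over the 28 pairs of groups, the replicate differences of one group and another correlated with r from -0.034 to 0.052 across probe sets (median 0.015).

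The 64 control probe sets were left out of the tests. Values were transformed as log2(signal + 4.10), where 4.10 is the 10th percentile of the table, so the changes of dim probe sets are smaller than the ratio of their signals. Probe sets whose mean log2 value over all arrays lay under the 25th percentile of those means were removed, which left 17059. A linear model with one mean for each of the 8 groups was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (8 residual degrees of freedom, prior degrees of freedom 12.0), with empirical Bayes moderation and a trend in the spread. Contrasts gave the salt response in each genotype and their average, each mutant against wild type and wer myb23 against cpc try averaged over the media, and the differences between salt responses. P-values were adjusted by the Benjamini-Hochberg method over all probe sets of a contrast, and a probe set was called changed at an adjusted p under 0.05. Tests were two-sided except the window permutations, which counted only the upper tail. At an unadjusted p under 0.05, 853 probe sets would pass by chance. The number of arrays, 2 per group, limits the precision. Arrays of the same design were simulated with 50 probe sets changed at each fold. On these the test of the wild type salt response recovered 24% of 2-fold and 70% of 4-fold changes, the averaged response 72% and 90%, and the comparison of cpc try with wild type 52% and 80%. Far fewer probe sets changed in the simulation than were called in these comparisons. The adjusted threshold depends on that number, so these rates need not hold for the data.

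Genes were taken from the platform annotation supplied with the table, in which 13513 probe sets had 1 gene, 503 had several and 8730 had none listed; probe sets with several genes or none were counted and not named. For a gene with several tested probe sets the brightest was used. Of the mutated genes only TRY could be named from it, and WER, MYB23, CPC and SCM were not analysed here. The genes named for each comparison followed a rule set before the data were examined. The tests, thresholds and alternatives were set then too, except the tests that the text gives as chosen later. The rule named the mutated genes, and the 8 largest rises and 8 largest falls among called genes whose compared arrays did not overlap. It also named up to 4 called members of each list with the smallest p, or up to 2 bright members where none was called. GL2, RHD6, EXPA7 and RD29A were named where measured. Not every gene that the rule names is printed below. The value of 1 root hair gene that this rule names is not reported here.

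Lists of genes were tested as groups with limma's camera with a preset correlation of 0.01, and again with the correlation estimated within each list, where they had at least 3 tested members. The lists of root hair, abscisic acid and dehydration, auxin, touch and calcium, and reference genes were fixed before the data were examined. The annotation names only part of the genes of other lists, so further lists were fixed from gene names after the annotation was seen and before the values were: root hair wall and peroxidase genes, late embryogenesis and cold or dehydration genes, cytosolic ribosomal proteins, core histones, photosystem and light-harvesting genes, plastid-encoded genes and families with a shared symbol (expansins, xyloglucan endotransglucosylases/hydrolases, UDP-glycosyltransferases, glutathione S-transferases, U-box ubiquitin ligases, SWEET transporters, CYP71B cytochromes P450, tetraspanins, serine carboxypeptidase-like proteins, calmodulin-like proteins, family 9 endoglucanases and beta-glucosidases). Camera p-values were adjusted over the lists of the same kind within a contrast. Markers of endodermis, xylem, phloem, root cap and stem cell niche had no tested member, so the cell types of the samples were not analysed here.

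Control probe sets for 25S ribosomal RNA, GAPDH and actin were compared between media with exact permutation tests over the 16 arrays, and the GAPDH and actin ratios also between genotypes (4 against 4 arrays), which was chosen after the comparisons were seen. Genes with a tested probe set, the brightest where there were several, were put in order along the chromosomes of the TAIR10.1 assembly. They were split into windows of about 100 genes. The spread of the shares of called genes over windows was tested with 10000 permutations of gene order, over all genes and with runs of adjacent called genes counted once. These window tests were added after the comparisons were seen. A first way of merging calls, within 10 genes, was replaced after its result was seen, because it made densely called comparisons look more even than chance; merging over gaps of up to 10 genes was later repeated with the same merging in each permutation. The alternatives were quantile normalization, median-centring, flooring or a larger offset (21.7, the 25th percentile) before taking logarithms, no filter or a filter at the 50th percentile, replicate number as a block, moderation without the trend or with robust estimation, a fit of only the arrays compared, each medium alone, an estimated correlation for lists, and leaving out each array in turn. Where this left a group with 1 array, that array was assumed to vary like the other groups. The figures were drawn with matplotlib 3.10.9.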

Results

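Transcript levels were measured on Affymetrix ATH1 arrays in root tips of Arabidopsis thaliana seedlings of 4 genotypes, each on 2 media, with 2 biological replicates per genotype and medium. The genotypes were the Columbia wild type and 3 mutants in which the pattern of hair and non-hair cells of the root epidermis is disturbed. WEREWOLF and MYB23, lost in the wer myb23 mutant, are MYB transcription factors of non-hair cells. CAPRICE and TRIPTYCHON, the genes named in the cpc try mutant, are small MYB proteins that act against that fate, and SCRAMBLED, the gene named in the scm mutant, is a receptor-like kinase that passes positional information to the epidermis. Seedlings were 5 days old when they were moved for 1 hour to standard medium or to medium with 140 mM NaCl, and about 30 root tips of about 5 mm were pooled per array. The series title sets the question as how the response to salt stress looks in mutants with defects in hair patterning.

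The mean MAS5 signal after trimming 2% of the values at each end was 250.03 on each of the 16 arrays, and the median signal ranged from 72.6 to 86.1. The correlation of log2 signals across probe sets between the replicates of a group ranged from 0.917 in wild type on salt to 0.963 in scm on salt. Between arrays of different groups it ranged from 0.857 to 0.959, so some of these pairs were more alike than some replicates. Probe sets are not independent replicates. The leading principal component, with 26.4% of the variance, separated the 8 arrays on salt from the 8 on standard medium, and the next, with 17.58%, separated the 4 cpc try arrays from the other 12. The number of arrays limits the precision of every value. Of the 17059 probe sets tested, 9577 (56.1%) had 1 gene in the annotation used here, so the gene groups described hold only part of each family.

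The transcript of the mutated gene was examined before the comparisons. TRY (AT5G53200), the only one of the 5 mutated genes with a probe set named in the annotation, had a mean signal of 811 ± 84.0 (SD, n = 2) in the arrays labelled cpc try on standard medium and 491 ± 13.7 (SD, n = 2) on salt. The wild type means were 48.8 ± 1.31 and 12.8 ± 3.94 (SD, n = 2 each). TRY was thus higher in the arrays labelled cpc try, by 4.42 ± 0.40 on the log2 scale (SE, limma adjusted p = 1.2e-07), in 4 of 4 arrays against 4 wild type arrays. The labels name the allele and give no lesion, so a signal from an altered transcript was not separated from one of the wild-type form. In wer myb23 against wild type, TRY was at -2.20 on standard medium and 0.94 on salt (limma adjusted p = 0.200 and 0.639). In scm it was at -1.94 and 1.24 (limma adjusted p = 0.299 and 0.700).

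**Figure D1:**
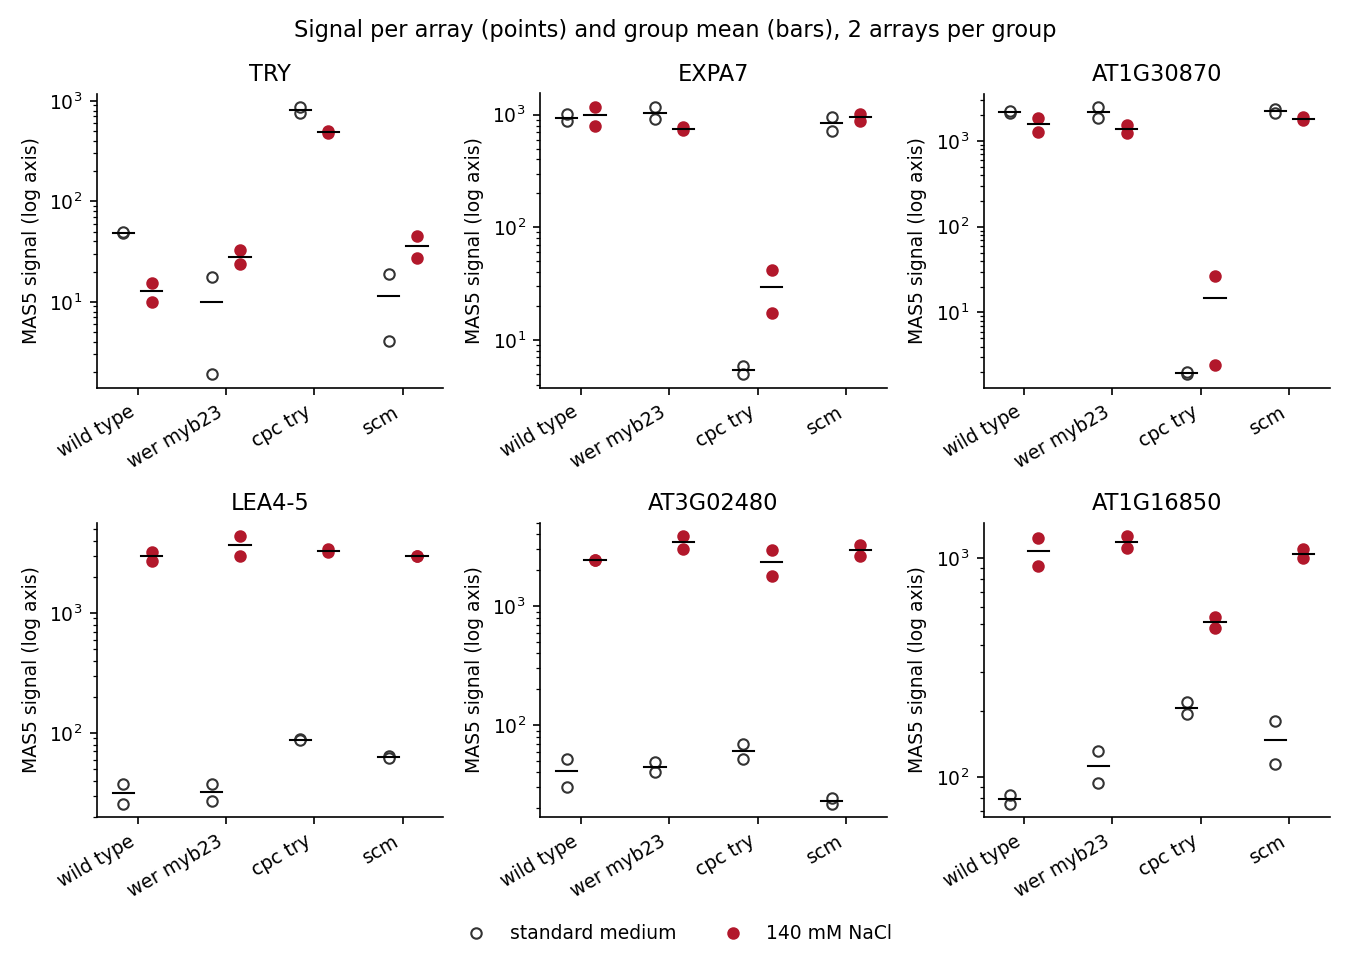
MAS5 signal (vertical log axes, arbitrary intensity units) of 6 genes in each of the 16 arrays, by genotype, with open points for standard medium, filled points for 140 mM NaCl and bars for the mean of 2 arrays. TRY was highest and EXPA7 and AT1G30870 lowest in cpc try, LEA4-5 and AT3G02480 were higher on salt in all 4 genotypes, and AT1G16850 rose less in cpc try (log2 1.28) than in wild type (log2 3.69).

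In wild type, 1 hour on salt raised transcripts of dehydration proteins and lowered those of xyloglucan endotransglucosylases/hydrolases. LEA4-5 (AT5G06760), a late embryogenesis abundant protein made in drying tissue, rose from a mean signal of 31.6 ± 8.31 to 2961 ± 366 (SD, n = 2 each), a log2 change of 6.39 ± 0.21 (SE, adjusted p = 5.9e-14). AT3G02480, listed here among the late embryogenesis genes, rose by 5.80 ± 0.25, and PUB19 (AT1G60190), a U-box ubiquitin ligase, by 5.56 ± 0.27 (SE). STZ (AT1G27730), a zinc finger repressor of abiotic stress responses, rose by 2.76 ± 0.27 (SE, adjusted p = 5.3e-07). XTH16 (AT3G23730) and XTH21 (AT2G18800), enzymes that cut and rejoin xyloglucan in the wall, fell by 3.23 ± 0.60 and by 2.88 ± 0.27 (SE).

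Of the 17059 probe sets, 1516 changed in wild type, 852 upward and 664 downward (758 and 767 after median-centring). The other largest rises were AT3G15670 (log2 4.96), AT1G24600 (4.77), LEA18 (AT2G35300, 4.56), the salt-induced serine-rich protein SIS (AT5G02020, 4.55) and AT1G49450 (4.32). The largest falls were AT1G61840 (log2 -4.07), AT3G11370 (-3.95), AT2G17590 (-3.75), AT3G01730 (-3.69), AT5G66815 (-3.53), AT2G44630 (-3.46), AT3G25790 (-3.34) and ACA.l (AT1G13210, -3.26), with adjusted p from 5.1e-05 to 0.0015. For each of these genes the salt arrays and the standard arrays did not overlap. CML38 (AT1G76650), a calmodulin-like protein, rose by 2.91 ± 0.62 (SE, adjusted p = 0.0039), CML42 (AT4G20780) fell by 1.99 ± 0.20, and EIN3 (AT3G20770), a transcription factor of ethylene signalling, rose by 0.66 ± 0.19 (SE, adjusted p = 0.037).

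By group, 3 of the 6 tested genes of abscisic acid and dehydration responses rose in wild type, and 5 rose when adjusted over the list alone. The group stood above the other genes in limma's camera test with adjusted p = 4.9e-07, and with adjusted p = 0.067 with an estimated correlation. The dehydrin LTI30 (AT3G50970) rose by 1.87 ± 0.17 and COR47 (AT1G20440) by 0.49 ± 0.13 (SE). Of 9 late embryogenesis and cold or dehydration genes 6 rose (camera adjusted p = 7.2e-11, and adjusted p = 0.022 with an estimated correlation). Of 7 xyloglucan endotransglucosylases/hydrolases 5 fell (camera adjusted p = 8.9e-06, and adjusted p = 0.022 with an estimated correlation). Of 19 root hair wall and peroxidase genes 3 fell (camera adjusted p = 0.00058, and adjusted p = 0.16 with an estimated correlation), and 6 of 117 cytosolic ribosomal protein genes fell (8.9e-06, and adjusted p = 0.36 with an estimated correlation). The count of changed probe sets was 984 without standard replicate 2 of wild type, 917 without its salt replicate 2, and 1010 when only the wild type arrays entered the fit.

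In wer myb23 on salt, LEA4-5 rose by 6.66 ± 0.21, AT3G02480 by 6.14 ± 0.25 and SIS by 5.97 ± 0.34 (log2, SE, n = 2 arrays per medium). COR15A (AT2G42540), a chloroplast protein of cold-treated plants, rose by 4.39 ± 0.91 (SE, adjusted p = 0.0022). XTH16 fell by 4.04 ± 0.60, and the pectin methylesterase ATPMEPCRB (AT4G02330) fell by 3.61 ± 0.47 (SE, adjusted p = 1.5e-05). In all, 1872 probe sets changed, 1020 upward and 852 downward (872 and 1004 after median-centring, 900 and 903 after quantile normalization).

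Other large rises in wer myb23 were AT3G15670 (log2 5.28), CCL (AT3G26740, 5.00), PUB19 (4.75) and AT1G24600 (4.71), and other large falls were AT1G44050 (-4.62), AT5G66815 (-4.53), AT1G61840 (-3.66), AT2G37820 (-3.59), AT5G48430 (-3.54) and the tetraspanin TET12 (AT5G23030, -3.46). STZ rose 11.3-fold (adjusted p = 1.4e-08). Of the 6 abscisic acid and dehydration genes 5 rose, and 6 when adjusted over the list alone (camera adjusted p = 2.6e-10, and adjusted p = 0.023 with an estimated correlation). Of the 9 late embryogenesis and cold or dehydration genes 6 rose (adjusted p = 0.014 with an estimated correlation), and 3 of the 7 xyloglucan endotransglucosylases/hydrolases fell (adjusted p = 0.041 with an estimated correlation). Of the 19 root hair wall and peroxidase genes 6 fell (camera adjusted p = 8.9e-05, and adjusted p = 0.10 with an estimated correlation), and 14 of the 117 ribosomal protein genes fell (camera adjusted p = 1.1e-06, and adjusted p = 0.31 with an estimated correlation). The count of 1872 was 1148 without standard replicate 1 of wer myb23, 1105 without its standard replicate 2, and 989 without its salt replicate 1.

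In cpc try on salt, LEA4-5 rose by 5.16 ± 0.21, AT1G24600 by 5.16 ± 0.25, AT3G02480 by 5.15 ± 0.25 and AT1G05340 by 5.08 ± 0.22 (log2, SE, n = 2 arrays per medium). STZ rose by 2.19 ± 0.27 (SE, adjusted p = 1.3e-05). XTH16 fell by 3.29 ± 0.60, XTH18 (AT4G30280) fell by 2.48 ± 0.25, and EXLA2 (AT4G38400), an expansin-like protein, fell by 2.99 ± 0.74 (SE). EXPA7 (AT1G12560), an expansin of root hairs, rose by 1.72 ± 0.28 (SE, adjusted p = 0.00025), from a mean signal of 5.40 ± 0.618 to 29.5 ± 17.3 (SD, n = 2 each); the 25th percentile of all signals was 21.7.

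In all, 1639 probe sets changed in cpc try, 925 upward and 714 downward (821 and 828 after median-centring). Other large rises were CCL (log2 4.74), SIS (4.60), PUB19 (4.42) and AT5G24080 (4.22), and other large falls were AT5G38790 (-4.27), AT2G46150 (-3.55), AT2G43140 (-3.08), AT4G25780 (-3.08), AT4G01140 (-3.06) and AT2G02680 (-3.04). ATMYC1 (AT4G00480), a helix-loop-helix protein of epidermal patterning, fell by 1.59 ± 0.31 (SE, adjusted p = 0.0014). Of the 6 abscisic acid and dehydration genes 3 rose, and 4 when adjusted over the list alone (camera adjusted p = 1.6e-07, and adjusted p = 0.056 with an estimated correlation). Of the 9 late embryogenesis and cold or dehydration genes 6 rose (adjusted p = 0.016 with an estimated correlation), and 4 of the 7 xyloglucan endotransglucosylases/hydrolases fell (adjusted p = 0.016 with an estimated correlation). Among the 117 ribosomal protein genes 3 fell and 2 rose (camera adjusted p = 0.0065, and adjusted p = 0.59 with an estimated correlation). The count of 1639 was 924 without standard replicate 2 of cpc try, 886 with only the cpc try arrays in the fit and 1079 without the trend in the spread.

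In scm, the largest rise was that of AT3G02480, by 6.76 ± 0.25, followed by AT3G15670 at 5.97 ± 0.57, PUB19 at 5.76 ± 0.27 and LEA4-5 at 5.48 ± 0.21 (log2, SE, n = 2 arrays per medium). STZ rose by 2.96 ± 0.27 (SE, adjusted p = 1.9e-07). XTH16 fell by 3.34 ± 0.60, XTH21 fell by 2.80 ± 0.27 and XTH18 fell by 2.48 ± 0.25 (SE). HTB1 (AT1G07790), a histone H2B, fell by 0.94 ± 0.18 (SE, adjusted p = 0.0018).

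In all, 1338 probe sets changed in scm, 805 upward and 533 downward. Other large rises were SIS (log2 5.26), AT1G24600 (5.13), LEA18 (4.89) and AT3G17520 (4.38), and other large falls were AT2G43140 (-4.14), AT1G61840 (-3.92), AT1G55430 (-3.72), AT5G48430 (-3.22), AT5G51310 (-3.19), AT3G46280 (-3.08) and AT2G03370 (-3.06). Of the 6 abscisic acid and dehydration genes 3 rose, and 5 when adjusted over the list alone (camera adjusted p = 7.9e-09, and adjusted p = 0.036 with an estimated correlation). Of the 9 late embryogenesis and cold or dehydration genes 6 rose (adjusted p = 0.013 with an estimated correlation), and 4 of the 7 xyloglucan endotransglucosylases/hydrolases fell (adjusted p = 0.029 with an estimated correlation). Of 7 core histone genes 3 fell (camera adjusted p = 0.00030, and adjusted p = 0.15 with an estimated correlation). Of the 19 root hair wall and peroxidase genes 1 fell (camera adjusted p = 0.028, and adjusted p = 0.35 with an estimated correlation), as did 2 of the 117 ribosomal protein genes (8.8e-06, and adjusted p = 0.35 with an estimated correlation). The count of 1338 was 792 and 844 without standard replicates 1 and 2 of scm, 839 and 694 without its salt replicates 1 and 2, and 891 without the trend in the spread.

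Averaged over the genotypes, AT3G02480 rose by 5.96 ± 0.13, LEA4-5 by 5.93 ± 0.11, PUB19 by 5.12 ± 0.13, SIS by 5.10 ± 0.17 and AT3G15670 by 5.09 ± 0.29 (log2, SE, 8 arrays per medium). AT1G61840 fell by 3.63 ± 0.39, XTH16 by 3.48 ± 0.30, AT5G66815 by 3.28 ± 0.32, AT3G46280 fell by 2.90 ± 0.13 and XTH21 by 2.67 ± 0.13 (SE). The largest rises and falls were picked among genes whose salt and standard arrays did not overlap, in the same direction, within each of the 4 genotypes. All 6 abscisic acid and dehydration genes rose, from COR47 at 0.53 ± 0.07 and COR15A at 2.55 ± 0.45 to LEA4-5 (camera adjusted p = 3.2e-08, and adjusted p = 0.044 with an estimated correlation); adjusted over the list alone the count was also 6. Of the 9 late embryogenesis and cold or dehydration genes 8 rose (adjusted p = 0.023 with an estimated correlation), and 5 of the 7 xyloglucan endotransglucosylases/hydrolases fell (adjusted p = 0.024 with an estimated correlation).

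In this average 4515 probe sets changed, 2324 upward and 2191 downward. The balance turned with the scaling, to 2017 upward and 2654 downward after median-centring and to 2064 and 2373 after quantile normalization. Of the 117 ribosomal protein genes 35 fell and 0 rose in limma (camera adjusted p = 3.1e-08, and adjusted p = 0.30 with an estimated correlation), with AT2G32220 at -1.24 ± 0.13 and AT5G59240 at -0.91 ± 0.13 (log2, SE) among them. The signal of the 25S ribosomal RNA control probe set was 2.29-fold higher on salt than on standard medium (8 arrays each, two-sided exact permutation p = 0.00031, adjusted p = 0.00093 over 3 control measures). Per genotype the ratio was 2.06 in wild type, 3.52 in wer myb23, 2.14 in cpc try and 1.56 in scm, where the arrays of the media overlapped (2012 and 5229 on standard medium, 5123 and 6204 on salt). The ratios of 3′ to 5′ signal of GAPDH and of 3′ to middle signal of actin differed between the media by less than the spread between arrays (exact permutation p = 0.661 and 0.676). Of 19 root hair wall and peroxidase genes 9 fell (camera adjusted p = 0.0017, and adjusted p = 0.22 with an estimated correlation), with AT5G04960 at -1.51 ± 0.21 (SE). None of the 3 reference genes or the 3 auxin genes passed (limma counts of 0 each), although 1 auxin gene rose when adjusted over the list alone, and among the 4 touch and calcium genes CML23 (AT1G66400) rose by 0.64 and CML42 fell by 2.12 ± 0.10 (SE). Adjusted over the list alone, 2 of those 4 rose and 1 fell.

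Of the 3105 probe sets that changed on salt in at least 1 genotype, 416 rose in all 4, 221 fell in all 4, and 9 rose in one genotype and fell in another. LEA4-5, AT3G02480, STZ and LTI30 were among those that rose in all 4, and XTH16, XTH21, CML42 and HTB1 among those that fell in all 4. Of the 852 that rose in wild type, 776 had a positive log2 change in the other 3 genotypes, and of the 664 that fell, 580 had a negative one. Between wild type and cpc try, 494 rises were shared, where independent calls would share 46.2 on average. Across probe sets the log2 responses of pairs of genotypes correlated with r from 0.466 (wild type and cpc try) to 0.626 (wer myb23 and scm), and probe sets are not independent replicates.

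**Figure D2:**
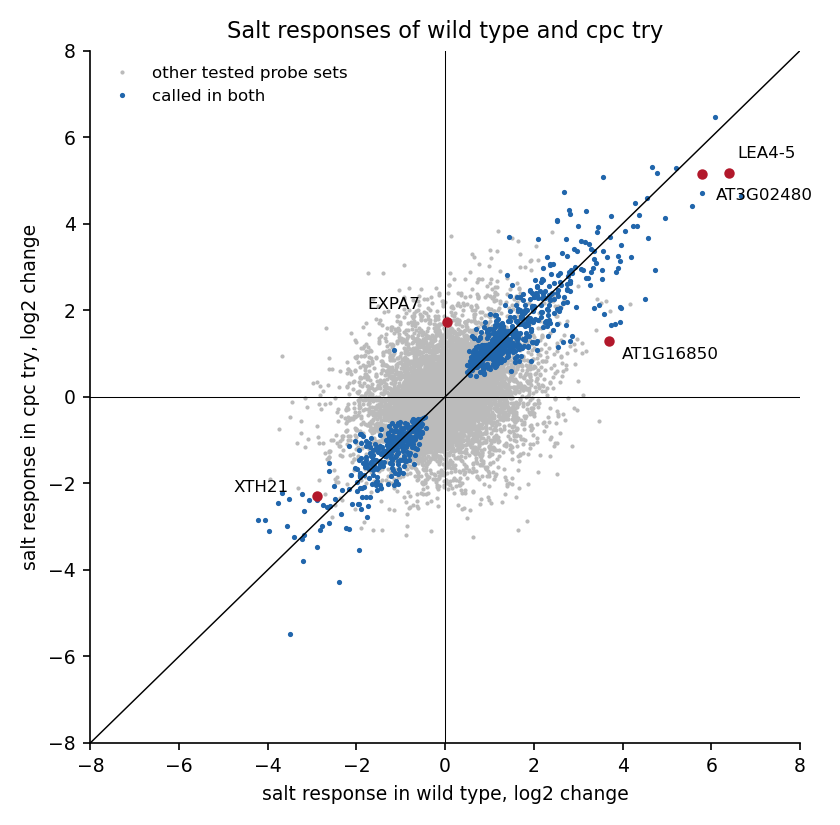
Log2 change on salt in cpc try (vertical axis) against that in wild type (horizontal axis) for the 17059 tested probe sets, with blue points for probe sets called in both and red points for 5 named genes; the diagonal marks equal changes. LEA4-5, AT3G02480 and XTH21 lay in the same direction in both genotypes, AT1G16850 below the diagonal (3.69 in wild type and 1.28 in cpc try) and EXPA7 above it (0.04 and 1.72).

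The genotype comparisons asked how the mutants differ from wild type over both media. In cpc try, transcripts of root hair genes were lower than in wild type. AT1G30870, a peroxidase listed here among the root hair wall genes, fell by 7.62 ± 0.29 on the log2 scale (SE, n = 4 arrays per genotype, adjusted p = 9.6e-14), with a mean signal on standard medium of 1.97 ± 0.0911 against 2169.7 ± 57.3 in wild type (SD, n = 2 each). EXPA7 and EXPA18 (AT1G62980), expansins of root hairs, fell by 5.79 ± 0.20 and by 4.83 ± 0.29 (SE), and the endoglucanase GH9C1 (AT1G48930) fell by 5.26 ± 0.32 (SE). ATMYC1 fell by 3.86 ± 0.22 (SE, adjusted p = 5.9e-11). In the control probe sets the log2 ratio of 3′ to 5′ GAPDH signal was 1.97 ± 0.59 in cpc try and 2.28 ± 0.13 in wild type, and that of 3′ to middle actin signal 1.93 ± 0.60 and 2.39 ± 0.18 (SD, n = 4 each, exact permutation p = 0.343 and 0.171). Several of these root hair signals in cpc try lay under the 25th percentile of the table (21.7), and the offset added before taking logarithms makes such changes smaller than the ratio of signals.

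All 3 tested root hair genes fell, also when adjusted over the list alone (camera adjusted p = 2.5e-09, and adjusted p = 0.0012 with an estimated correlation). The member whose value is not reported here fell by much less than EXPA7 and EXPA18. Of 19 root hair wall and peroxidase genes 13 fell and 2 rose (camera adjusted p = 6e-15, and adjusted p = 0.0076 with an estimated correlation). HRGP1 (AT3G54590), a hydroxyproline-rich wall protein, fell by 3.92 ± 0.24 and AT5G04960 fell by 4.48 ± 0.29, while AT2G39040 rose by 1.21 ± 0.16 and AT3G28550 by 0.45 ± 0.11 (SE). Of 7 xyloglucan endotransglucosylases/hydrolases 3 rose, among them XTH33 (AT1G10550) by 1.95 ± 0.46 and XTH18 by 1.05 ± 0.18 (camera adjusted p = 8.7e-05, and adjusted p = 0.038 with an estimated correlation). Of 7 photosystem and light-harvesting genes 5 fell, LHCB4.2 (AT3G08940) by 1.85 ± 0.25 and PSAE-1 (AT4G28750) by 1.66 ± 0.20 (camera adjusted p = 0.00077, and adjusted p = 0.20 with an estimated correlation). Of 69 plastid-encoded genes 8 fell and 2 rose (0.0011, and adjusted p = 0.42 with an estimated correlation).

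In all, 1981 probe sets differed between cpc try and wild type, 803 higher and 1178 lower in cpc try. Besides TRY, the largest rises were AT5G19100 (log2 3.24), AT3G29410 (3.13), AT5G01870 (3.12), AT5G24240 (3.10), AT5G51930 (2.85), AT2G33850 (2.81) and AT5G51440 (2.63), and other large falls were AT2G47540 (-6.88), AT4G22460 (-5.32), AT3G49960 (-4.94), GSTU28 (AT1G53680, -4.91) and AT3G12540 (-4.88). WRKY53 (AT4G23810), a transcription factor of senescence and defence, rose by 1.17 ± 0.31, and LEA4-5 rose by 0.77 ± 0.15 (SE), with 1.39 on standard medium (adjusted p = 0.00019) and 0.16 on salt (adjusted p = 0.760). Falls were 59.5% of the calls on the values as deposited, 54.0% after quantile normalization (892 rises and 1046 falls) and 34.4% after median-centring (1609 rises and 842 falls). Past 2-fold, 548 fell and 184 rose as deposited, 455 and 259 after quantile normalization and 430 and 303 after median-centring. Median-centring moved the median log2 difference of all probe sets by 0.13, to 0.11. The count was 1064 on standard medium alone, 953 on salt alone and 1304 with only the arrays of both genotypes in the fit.

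Along the chromosomes of the TAIR10.1 assembly, the share of genes that were lower in cpc try was uneven. In 94 windows of neighbouring tested genes (9387 genes, 6.78% of which fell), it ran from 0 of 102 genes between AT5G08430 and AT5G11560 in limma's calls, and 1 gene in each of the 3 windows from AT1G73440 to AT1G80970, to 16 of 102 genes (15.7%) between AT5G41350 and AT5G43880. The variance between windows was 1.72 times that of independent genes (permutation p = 1e-04, the smallest that 10000 permutations can give). The rises on salt averaged over the genotypes were also uneven, with 1.46 times that variance (permutation p = 0.0023, adjusted p = 0.011 over 14 tests). Among the 102 genes of the window without a fall, 6 rose.

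**Figure D3:**
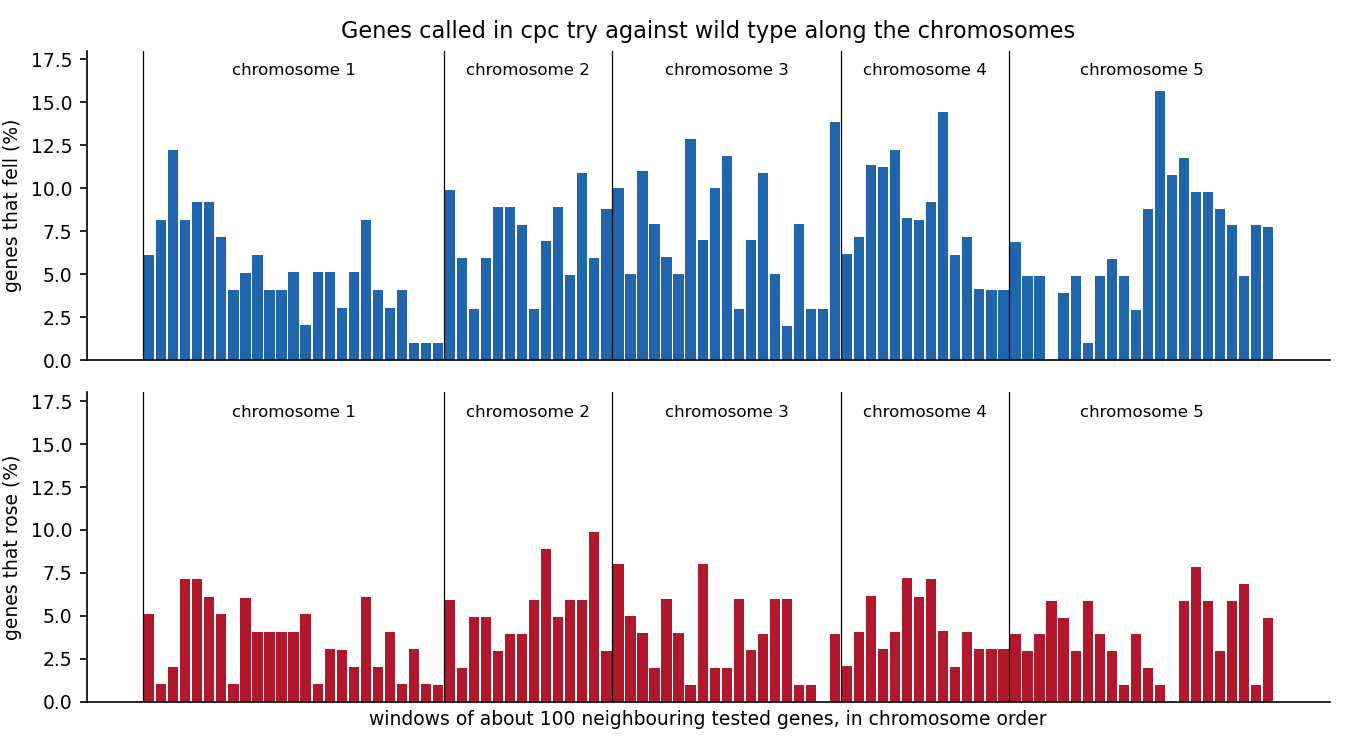
Share of genes (vertical axes, %) that fell (upper panel, blue) or rose (lower panel, red) in cpc try against wild type, in 94 windows of 97 to 103 neighbouring tested genes in chromosome order (horizontal axis); lines mark the starts of chromosomes 1 to 5. The share of falls ranged from 0 to 15.7%, and 5 windows lay under 2% and 14 above 10%.

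In wer myb23, few transcripts differed from wild type over both media. AT5G35940 fell by 1.61 ± 0.17 on the log2 scale (SE, n = 4 arrays per genotype, adjusted p = 9.4e-05), and AT2G43590 and AT4G29690 fell by 1.39 ± 0.16 and by 1.00 ± 0.12 (SE). For AT2G43590 the log2 difference was -1.02 on standard medium (adjusted p = 0.128) and -1.77 on salt (adjusted p = 0.00087). ATPMEPCRB, the pectin methylesterase, fell by 2.04 ± 0.33 (adjusted p = 0.0049), and CYP71B23 (AT3G26210), a cytochrome P450, rose by 1.52 ± 0.26 (SE, adjusted p = 0.0058). On standard medium alone these log2 differences were -0.33 and 0.66 (adjusted p = 0.896 and 0.647), on salt alone -3.76 and 2.39 (adjusted p = 0.00087 and 0.0048). DI19 (AT1G56280), a drought-induced zinc finger protein, rose by 0.84 ± 0.17, and PRH75 (AT5G62190), an RNA helicase, by 0.69 ± 0.13 (SE). The root hair expansin EXPA7 had a log2 difference of -0.11 ± 0.20 (SE, adjusted p = 0.863). In the control probe sets for RNA quality, the log2 ratio of 3′ to 5′ GAPDH signal was 1.61 ± 0.10 in wer myb23 and 2.28 ± 0.13 in wild type, and that of 3′ to middle actin signal 1.93 ± 0.16 and 2.39 ± 0.18 (SD, n = 4 each), without overlap (exact permutation p = 0.029 each, the smallest that 4 against 4 arrays can give, adjusted p = 0.076 over 8 tests). The wild type arrays were the same in every mutant comparison, so a deviation in them would appear in each. CYP71B23 was also higher in cpc try than in wild type on salt (log2 2.07, limma adjusted p = 0.0010), with 0.19 on standard medium. Its difference was thus not particular to wer myb23.

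In all, 87 probe sets differed between wer myb23 and wild type, 31 higher and 56 lower, and 2158 had an unadjusted p under 0.05 where 853 would by chance. After median-centring this balance turned (87 higher and 36 lower), while after quantile normalization it was kept (34 higher and 61 lower). The other genes with the largest changes were AT5G15950 (log2 1.43), AT2G27830 (1.13, with 1.54 on standard medium and 0.72 on salt), AT5G06800 (0.84), AT1G06720 (0.79) and PHOS34 (AT4G27320, 0.75), and AT1G14550 (-1.39), AT2G23910 (-1.32, with -2.03 on standard medium and -0.61 on salt), AT3G47070 (-1.03) and AT5G47550 (-0.99). Of the 3 root hair genes 0 passed in limma, also when adjusted over the list alone. Of the 19 root hair wall and peroxidase genes AT5G06630 and AT2G39040 fell, by 0.96 ± 0.20 and by 0.92 ± 0.16 (camera adjusted p = 0.0042, and adjusted p = 0.32 with an estimated correlation). Camera also placed the serine carboxypeptidase-like, photosystem and plastid-encoded groups low, with adjusted p of 0.031, 0.014 and 0.031 and with adjusted p = 0.32, 0.47 and 0.57 with an estimated correlation, and the ribosomal protein group low (0.0042, and adjusted p = 0.57 with an estimated correlation), a direction that turned under quantile normalization (0.818). The count of 87 was 15 on standard medium alone, 35 on salt alone, 12 without the trend in the spread, 144 without salt replicate 2 of wild type, 52, 28 and 53 without standard replicates 1 and 2 and salt replicate 1 of wer myb23, and 206 without either salt replicate of cpc try.

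In scm, still fewer transcripts differed from wild type. AT3G19430 rose by 1.00 ± 0.12 on the log2 scale (SE, n = 4 arrays per genotype, adjusted p = 0.00017), and the endoglucanase GH9C2 (AT1G64390) rose by 0.84 ± 0.17 (SE, adjusted p = 0.043). HTB2 (AT5G22880), a histone H2B, fell by 0.86 ± 0.13 (SE, adjusted p = 0.0069), and AT4G39675 and AT5G35940 fell by 1.01 ± 0.17 and by 0.96 ± 0.17 (SE). EXPA7 had a log2 difference of -0.10 ± 0.20 (SE, adjusted p = 0.885). The GAPDH log2 ratio was 1.79 ± 0.16 in scm and that of actin 2.06 ± 0.09 (SD, n = 4 each), lower than in wild type by 0.48 (exact permutation p = 0.029) and 0.32 (exact permutation p = 0.057), with adjusted p = 0.076 and 0.114 over the 8 tests. Against the same wild type arrays, AT5G35940 was also lower in wer myb23 and GH9C2 also higher in cpc try.

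In all, 24 probe sets differed between scm and wild type, 11 higher and 13 lower, and 1921 had an unadjusted p under 0.05. The other named genes were AT4G39200 (log2 0.76), AT4G30460 (-0.95), AT3G47800 (-0.81), AT3G56360 (-0.78) and AT4G30450 (-0.66). Of the 6 abscisic acid and dehydration genes 0 passed in limma and 1 rose when adjusted over the list alone; the camera adjusted p was 0.85. After median-centring, which moved the median of all probe sets by 0.11, the count was 67, 57 higher and 10 lower. It was 9 on standard medium alone, 1 on salt alone and 3 without the trend in the spread, and 10, 66 and 15 without standard replicate 1 and salt replicates 1 and 2 of wild type, 45 without either salt replicate of cpc try, and 6, 7 and 6 without standard replicate 1 and salt replicates 1 and 2 of scm.

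The wer myb23 and cpc try mutants, known for more and fewer hair cells than wild type, were compared directly over both media. Hair cells were not counted here. Root hair transcripts were higher in wer myb23, AT1G30870 by 7.54 ± 0.29, AT2G47540 by 6.94 ± 0.16, EXPA7 by 5.68 ± 0.20 and EXPA18 by 4.74 ± 0.29 (log2, SE, n = 4 arrays per genotype). ATMYC1 was higher by 4.26 ± 0.22 and the expansin EXPA8 (AT2G40610) by 3.52 ± 0.38 (SE, adjusted p = 8.9e-07). TRY was lower in wer myb23, at -5.05 ± 0.40 (SE, adjusted p = 1.3e-08). The cpc try arrays are the same as in the comparison with wild type, so both comparisons share their values. In wer myb23 against wild type, EXPA7 was at 0.13 on standard medium and -0.36 on salt, and EXPA18 at -0.12 and -0.06. None of these passed. In cpc try both genes were lower than in wild type on both media, so their difference here lay in the cpc try arrays.

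In all, 2389 probe sets differed, 1389 higher and 1000 lower in wer myb23 (1176 and 1191 after median-centring). Other large differences were those of AT2G34910 (log2 5.28), GH9C1 (5.27), GSTU28 (5.14) and AT4G22460 (4.91), and of AT5G19100 (-4.18), AT5G01870 (-3.42), AT3G29410 (-3.33), AT5G24240 (-2.87), AT1G33670 (-2.75), AT1G24430 (-2.73) and AT5G51930 (-2.71). All 3 root hair genes were higher, also when adjusted over the list alone (camera adjusted p = 3.6e-09, and adjusted p = 0.0013 with an estimated correlation), and 13 of the 19 root hair wall and peroxidase genes were higher and 2 lower (adjusted p = 0.024 with an estimated correlation). Among the 3, the member whose value is not reported here differed by much less than EXPA7 and EXPA18. Of 16 expansins 6 were higher and 1 lower (camera adjusted p = 0.016, and adjusted p = 0.072 with an estimated correlation), and 4 of the 7 xyloglucan endotransglucosylases/hydrolases were lower (adjusted p = 0.033 with an estimated correlation). The ribosomal protein group stood low in camera (13 lower and 8 higher of 117, adjusted p = 0.040, and adjusted p = 0.73 with an estimated correlation), a direction that turned under quantile normalization (0.184). The count was 1122 on standard medium alone and 1465 on salt alone.

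The last comparisons asked whether the size of the salt response differed between genotypes. Between wer myb23 and cpc try, 15 named genes did. AT1G16850, listed among the late embryogenesis and cold or dehydration genes, rose on salt by 3.36 in wer myb23 and by 1.28 in cpc try, a difference of 2.08 ± 0.32 on the log2 scale (SE, 2 arrays in each of 4 groups, adjusted p = 0.0086). LEA4-5 rose by 6.66 and 5.16 (difference 1.50 ± 0.30, adjusted p = 0.037), and its mean signal on standard medium was 88.0 ± 1.48 in cpc try and 32.01 ± 7.27 in wer myb23 (SD, n = 2 each). EXPA7 changed by -0.45 in wer myb23 and 1.72 in cpc try (difference -2.17 ± 0.39, adjusted p = 0.024), with cpc try signals near the lower end of the scale. AT5G06630, of the root hair wall group, changed by -1.06 and 1.08 (difference -2.14 ± 0.40, adjusted p = 0.028).

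In that comparison 31 probe sets passed, 13 with the larger value in wer myb23 and 18 with the smaller (12 and 11 after median-centring), and 1397 had an unadjusted p under 0.05. The other named genes were AT4G36010 (log2 difference 2.54), AT2G41190 (2.11), AT4G16980 (1.88), AT3G49220 (1.55), AT5G65470 (1.44), AT5G48900 (1.19), AT5G48430 (-2.01), AT5G62150 (-1.89), AT2G15830 (-1.67), AT3G10720 (-1.25) and AT3G52500 (-1.07). Of the 6 abscisic acid and dehydration genes 1 differed, also when adjusted over the list alone (camera adjusted p = 0.0033, and adjusted p = 0.13 with an estimated correlation), and of the 19 root hair wall and peroxidase genes 1 differed (camera adjusted p = 0.00049, and adjusted p = 0.31 with an estimated correlation). Camera also placed the late embryogenesis and cold or dehydration genes higher (adjusted p = 0.021, and adjusted p = 0.32 with an estimated correlation) and the CYP71B and ribosomal protein genes lower (adjusted p = 0.046 each, and adjusted p = 0.31 and 0.70 with an estimated correlation) in the response of wer myb23. The count of 31 was 5 with only the arrays of both genotypes in the fit and 1 without the trend in the spread. It was 8, 2 and 8 without standard replicates 1 and 2 and salt replicate 1 of wer myb23, 10, 19 and 83 without standard replicates 1 and 2 and salt replicate 1 of cpc try, 15 without either standard replicate of scm and 17 without either salt replicate of scm.

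Against wild type, the salt response of cpc try differed at 3 probe sets, with 1480 at an unadjusted p under 0.05. AT1G16850 rose by 1.28 in cpc try and by 3.69 in wild type (difference -2.41 ± 0.32, SE, adjusted p = 0.0052). The others had no gene in the annotation used here. For EXPA7 the difference between cpc try and wild type was 1.68 ± 0.39 (SE, adjusted p = 0.190). Camera placed the 8 CYP71B and the 19 root hair wall and peroxidase genes higher in the response of cpc try (adjusted p = 0.0051 and 0.011, and adjusted p = 0.12 and 0.46 with an estimated correlation), with 0 members past the threshold in limma. The count of 3 was 1 after quantile normalization, 1 with the larger offset, 1 with robust moderation and 1 with only the arrays of both genotypes in the fit. Without a single array it was 15, 19, 41 and 6 (standard replicates 1 and 2 and salt replicates 1 and 2 of wild type), 1, 13, 23 and 18 (those of cpc try in the same order) and 1 without either standard replicate of wer myb23.

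The response of wer myb23 differed from that of wild type at 1 probe set, without a gene in the annotation used here (adjusted p = 0.023), and 860 had an unadjusted p under 0.05. Camera placed the 6 abscisic acid and dehydration genes higher in the response of wer myb23 (adjusted p = 0.012, and adjusted p = 0.55 with an estimated correlation), with 0 members past the threshold in limma, also when adjusted over the list alone. That count was 0 in limma after quantile normalization, with the larger offset, without the filter, with the stricter filter and with only the arrays of both genotypes. Without a single array it was 0, 4 and 7 (standard replicates 1 and 2 and salt replicate 1 of wild type), 0 without either salt replicate of wer myb23 or of scm, and 5 when all arrays were kept and the trend in the spread was left out. The response of scm differed from that of wild type at 0 probe sets in limma, with 764 at an unadjusted p under 0.05, and at 1, 4, 6 and 1 without standard replicates 1 and 2 and salt replicates 1 and 2 of wild type. LEA4-5, which rose in both, had a difference of -0.91 between scm and wild type that did not pass. On simulated arrays of the same design, with 50 probe sets changed at each fold, the test of a difference between the responses of wer myb23 and cpc try recovered 12% of 2-fold, 46% of 4-fold and 80% of 8-fold differences. These rates depend on how many probe sets change. The comparisons with wild type were not simulated.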

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

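Of the tests below, that of a weaker salt treatment was chosen only after the differing responses were seen.

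Salt responses that differed between genotypes were singled out by the test of the difference itself. Against wild type, 1 probe set differed in wer myb23 and 3 in cpc try, among them AT1G16850 (log2 difference -2.41). Between wer myb23 and cpc try 31 probe sets differed, with named genes AT4G36010 (2.54), AT2G41190 (2.11), AT1G16850 (2.08), AT4G16980 (1.88), AT3G49220 (1.55), LEA4-5 (1.50), AT5G65470 (1.44), AT5G48900 (1.19), EXPA7 (-2.17), AT5G06630 (-2.14), AT5G48430 (-2.01), AT5G62150 (-1.89), AT2G15830 (-1.67), AT3G10720 (-1.25) and AT3G52500 (-1.07). A further measurement outside the comparisons, the 25S ribosomal RNA control probe set, was 2.29-fold higher on salt.

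For the responses that differed between wer myb23 and cpc try, a weaker salt treatment of the cpc try arrays would shrink them all. However, 9 of the 31 were larger in size in cpc try, EXPA7 with its low signals among them, and 15 had opposite signs. This argues against a weaker treatment as the whole cause, although the 31 were picked for a difference on these same arrays. Over the probe sets called in scm the median log2 response was nevertheless smallest in cpc try (1.02, against 1.05 in wild type and 1.16 in wer myb23). A slightly weaker treatment therefore stays open. Signals near the lower end in the arrays labelled cpc try might account for some of the differences: 5 of the 31 probe sets, EXPA7 among them, had a cpc try mean under the 25th percentile of the table, and for these the test was undecided. The other 26 had both cpc try means at or above it. The mutation itself stays open as a hypothesis and was not tested apart from the single pools of seedlings behind each array. The number of such probe sets depended on single arrays (2 without standard replicate 2 of wer myb23, 83 without salt replicate 1 of cpc try).

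The higher 25S signal on salt raised the question whether ribosomal RNA content moved the probe sets called on salt. Within the 8 replicate pairs, the slope of the salt score (the mean log2 value of probe sets that rose on salt minus that of those that fell) on the 25S signal was 0.0748 ± 0.0977 (SE), which accounted for 5.24% ± 6.85 (SE) of the salt score's difference between media. This share stayed under the 50% set beforehand for this explanation. The slope rested mainly on scm on standard medium, the pair whose 25S signals differed most (2012 and 5229). The salt score was also built from probe sets called on the same arrays. The explanation was therefore not excluded. A difference in ribosomal RNA between salt-treated and untreated roots stays open as a biological explanation of the control signal and was not tested.

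Other splits of the arrays were counted for the comparisons with at least 4 arrays on each side. For the averaged salt response, 1 of 100 splits into 8 and 8, the real one, gave as many called probe sets (4449 with genotype as a covariate), and the highest other gave 1603. With the medium as a covariate, 1 of 34 splits of the 8 arrays, again the real one, gave as many for wer myb23 against wild type (93, highest other 6), cpc try against wild type (1310, highest other 0 in limma), scm against wild type (31, highest other 3) and wer myb23 against cpc try (2020, highest other 0). No other split counted gave as many, which is the smallest share that these splits can give, and it was not adjusted over the comparisons. The splits did not keep the media, or for the averaged salt response the genotypes, balanced between the sides. Fewer splits of the 8 arrays would keep the media balanced, and the smallest possible share would then be larger. The share is therefore not an exact p-value, and chance was not excluded. The other splits leave the real difference in the spread, so low counts in them were to be expected. The splits also cannot tell the genotype from another difference between the same arrays. The split by medium could not be fitted.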

How the results depend on the processing

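No test of this part was chosen after the results were seen. Of 4924 values of named genes under other settings 4582 kept their direction and their side of the threshold, 336 lost the call, 5 gained one and 1 turned: LEA4-5 in wer myb23 against cpc try, which was 0.14 on salt medium alone (adjusted p = 0.789). With one array left out, 7015 of 7632 were the same, 610 lost the call, 7 gained one and none turned. Of 48 list calls, 19 held with an estimated correlation. Of 523 list values under other settings 460 were the same, 61 lost the call and 2 turned, both the ribosomal protein list under quantile normalization, in wer myb23 against wild type (adjusted p = 0.818) and in wer myb23 against cpc try (adjusted p = 0.184).

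Counts that moved by over 1.5 times were these. With only the arrays compared in the fit, which leaves fewer arrays to estimate the spread, the salt response was 1010 in wild type and 886 in cpc try, cpc try against wild type was 1304, and the differences of responses were 0 (wer myb23 and wild type, limma), 1 (cpc try and wild type) and 5 (wer myb23 and cpc try). Without the trend the salt response was 1079 in cpc try and 891 in scm, wer myb23 against wild type was 12 and scm against wild type 3, and the differences of responses were 5 (wer myb23 and wild type), 2 (scm and wild type) and 1 (wer myb23 and cpc try). On standard and on salt medium alone, which compare fewer arrays, the counts were 15 and 35 for wer myb23 against wild type, 1064 and 953 for cpc try, 9 and 1 for scm, and 1122 and 1465 for wer myb23 against cpc try. With replicate number as a block, wer myb23 against wild type was 133 and its difference of responses 2. Median-centring gave 67 for scm against wild type. The difference of responses between wer myb23 and wild type was 0 in limma under quantile normalization, the 25th percentile as offset, no filter and the filter at the 50th percentile, and that between cpc try and wild type was 1 under quantile normalization, the larger offset and robust moderation. The cause was not tested for the settings whose construction does not show it.

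With each array left out in turn, the salt response ranged from 917 to 1703 in wild type, 989 to 2115 in wer myb23, 924 to 1721 in cpc try, 694 to 1496 in scm and 3814 to 4594 averaged. Genotype counts ranged from 28 to 206 for wer myb23, 1558 to 2141 for cpc try and 6 to 66 for scm against wild type, and from 1731 to 2472 for wer myb23 against cpc try. Differences of responses ranged from 0 to 7 (wer myb23), 1 to 41 (cpc try) and 0 to 6 (scm) against wild type and from 2 to 83 between wer myb23 and cpc try, and list calls from 40 to 52. The signal over background limits dim probe sets: under the 25th percentile of the table, 21.7, changes are compressed by the offset.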

Other observations

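The window tests and the test of falls past 2-fold were chosen only after the comparisons were seen.

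Members of other gene families passed on salt averaged over the genotypes, where 4515 of all 17059 probe sets did; none of these families passed as a group in camera. Of 35 UDP-glycosyltransferases, enzymes that attach sugars to hormones and metabolites, 8 rose and 9 fell, UGT87A2 (AT2G30140) by 1.84 ± 0.10 and UGT74B1 (AT1G24100) at -0.95 ± 0.12 (log2, SE; camera adjusted p = 0.98). Of 13 glutathione S-transferases 1 rose and 4 fell, GSTU27 (AT3G43800) at -1.55 ± 0.12 and ATGSTF13 (AT3G62760) at -0.99 ± 0.13 (camera adjusted p = 0.49). Among 16 expansins EXPA9 (AT5G02260) and EXLA1 (AT3G45970) rose by 0.84 ± 0.08 and 1.07 ± 0.09, and 4 fell, EXPB1 (AT2G20750) at -1.58 ± 0.11 (camera adjusted p = 0.98). Of 8 U-box ubiquitin ligases PUB19 and PUB24 (AT3G11840, 1.35 ± 0.27) rose (camera adjusted p = 0.26), and of 23 serine carboxypeptidase-like genes 1 rose and 4 fell, scpl40 (AT3G63470) at -1.69 ± 0.10 (camera adjusted p = 0.27). Of 7 core histone genes 4 fell and 1 rose (camera adjusted p = 0.057), among them HTB1 at -0.94 ± 0.09 and AT2G28720 at -1.13 ± 0.12. Family 9 endoglucanases had 2 rises and 2 falls of 11, SWEET transporters 2 rises and 1 fall of 12, CYP71B cytochromes P450 1 rise and 2 falls of 8, tetraspanins 1 rise and 2 falls of 9, beta-glucosidases 2 rises and 1 fall of 13 and calmodulin-like proteins 2 rises and 1 fall of 6.

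In cpc try against wild type, UGT87A2 rose by 1.84 ± 0.14, AT2G40010, listed among the ribosomal protein genes, was at -4.04 ± 0.29, GSTU26 (AT1G17190) at -0.81 ± 0.11 and GSTL3 (AT5G02790) at -1.26 ± 0.31 (log2, SE). Of 11 family 9 endoglucanases 3 rose, GH9C2 by 1.14 ± 0.17 and GH9C3 (AT4G11050) by 1.33 ± 0.33, and GH9C1 fell by 5.26 ± 0.32. DI21 (AT4G15910), listed among the dehydration genes, was at -2.32 ± 0.12 in cpc try, and its averaged salt response of 0.15 did not pass.

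In the arrays labelled cpc try, falls were 58.7% of the calls past 2-fold after median-centring and 63.7% after quantile normalization, against 74.9% as deposited. This argues against the scaling of the arrays as the whole cause of the excess past 2-fold, although centring moved that balance too. Over all calls the falls were 59.5% as deposited and 34.4% after median-centring. Scaling was therefore not excluded as the cause of the excess over all calls. A first test over all calls was withdrawn, because centring itself moves that balance, and the test past 2-fold replaced it. The uneven spread of the falls along the chromosomes was weighed apart from the excess of falls. Neighbouring gene families counted several times are argued against, since the unevenness had permutation p = 0.00020 with runs of adjacent falling genes counted once, a way of merging chosen after a first one, within 10 genes, had been seen; with gaps of 2 to 10 genes merged alike in data and permutations p ran from 0.0012 to 0.025. A candidate explanation is that the mutant carries chromosome segments of another accession, whose sequence differences lower the signal of probes designed on Columbia: the shares of falls in neighbouring windows correlated with r = 0.39 (permutation p = 0.00030, adjusted p = 0.0042 over 14 tests), while those of rises in cpc try (r = 0.15, p = 0.064) and of falls on salt averaged over the genotypes (r = -0.03, p = 0.56, both by permutation) did not pass. The rises in cpc try were fewer genes than the falls (381 against 636), and their correlations were not compared with each other. That one passed and the other did not therefore does not show that falls and rises differ. The labels give Columbia for all arrays, and effects of the mutations on neighbouring genes stay open and were not tested.

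Among the other 11 tests of neighbouring windows, the rises in wer myb23 against cpc try, which share the cpc try arrays, had r = 0.32 (permutation p = 0.00060). The rises on salt in wer myb23 had r = 0.24 (upper-tail permutation p = 0.0085, adjusted p = 0.040) against r = -0.29 for the falls there (p = 0.997 in the same tail). The rises on salt averaged over the genotypes were uneven between windows too (dispersion 1.46, permutation p = 0.0023, and 0.033 with runs counted once), although their neighbouring windows did not correlate (r = 0.05, permutation p = 0.30). Both media share the genotype, so a lower signal of the same probes on both media does not directly account for these salt results. Whether accession segments could give them in another way was not tested. After median-centring the falls in cpc try had r = 0.42 (permutation p = 1e-04, the smallest the permutations can give).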
